A study of Mus musculus with 46 samples.

How the data were processed

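Messenger RNA was measured by 10x Visium spatial transcriptomics in 46 sections of Swiss-rolled mouse intestine on 13 slides: 15 SPF, 15 GF and 10 FMT sections over 5 gut segments, 4 SPF colon sections of a DSS series and 2 dark colon sections. The authors deposited, for each section, a matrix of raw UMI counts per gene and spot with spot positions. Per the submitters' processing notes these counts were made with Space Ranger on the mm10 mouse genome, and per the file headers with spaceranger 1.2.1; filters beyond the selection of tissue spots are not given in the sources used here. Per the labels' protocols the tissue was fresh-frozen in OCT and polyadenylated RNA was captured. Because each transcript is counted from its 3' end by UMI, the counts do not depend on transcript length, and near-identical gene copies (defensins, Saa, Reg3, mast cell proteases) can share reads.

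All deposited matrices held only spots marked as tissue. Counts ran over 32285 genes, 78 of which share a symbol with another and were kept apart by row. Depth per section was 33926458 to 107883762 UMIs over 1765 to 4639 spots, so a gene at 1 CPM lies far above a floor of 3 counts in every section, and the spread between sections, not counting error, sets the precision of the tested comparisons. Between 1 and 104 spots of a section held under 1000 UMIs and were kept. Spots are not replicates: the counts of all spots of a section were summed, and the section is the unit of every test.

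Groups came from titles and treatment tags. One section has a title and a treatment tag that name different groups (FMT and GF) and was placed by its title. Replicate numbers of the labels name sections; no label names an animal.

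The following choices were made before the data were examined: groups, comparisons, tests, gene lists, the rule for named genes and the alternatives, except where the text says that an alternative was chosen after seeing the data. Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr, libraries scaled by TMM, dispersions estimated with the robust option, and differences tested with glmQLFit (robust) and glmQLFTest; a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels beside a test are CPM with the TMM factors of the same fit. The SE of a log2 difference is its size divided by the square root of the F statistic. Segment comparisons used a fit of the 15 SPF sections, and GF, FMT and SPF comparisons a fit of the 8 sections of a segment. Differences of the GF effect between segments were an F-test of 4 interaction terms over 30 sections. For the rolls, spots were ordered by distance from the centroid of the section's spots, the outer and inner bands (1 in 3 of the spots each) were summed, and the section was a block; this distance is a proxy for position along the gut.

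In all, 43 gene lists (tissue functions, cell types, immune pathways, clock) were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation, for lists with at least 5 tested members, adjusted over lists. List members called were counted over all genes tested and adjusted over the list alone. The text describes the lists that lead the comparisons with at least 20 called genes and gives the number of all lists past camera in each comparison where it was run. Named genes were chosen by a rule: among called genes with a mean log2 CPM of at least 3 and no overlap between groups, the 8 largest rises and 8 largest falls (4 and 4 for FMT, 5 and 5 in the duodenum and jejunum), without predicted genes, immunoglobulin segments, sex-linked genes and haemoglobins. The rule adds up to 4 called members of each list past camera, fixed sentinel genes in every comparison, and in FMT comparisons the genes named for GF. From these the text gives a selection; a few genes of the lists are counted in them but not reported here by name. Ggt1, Tmigd1, Slc7a9, Lama1 and the mean GF effects are named outside the rule where they appear for the interaction or in the closing section, and were chosen after their values were seen.

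With 1 section per label, the DSS series allowed no test. The dark sections, 1 of each status, were compared within status without a test, and no fit that pools both statuses was run. Genes were taken by a 4-fold rule on CPM with a pseudocount of 1 CPM and at least 20 CPM in the higher section. Levels carry exact Poisson 95% intervals, which cover counting error only. A list median was placed among 10000 random lists of the same size drawn within 20 bins of expression over genes of at least 1 CPM; SPF colon sections were placed the same way as a background, which was chosen after seeing the data. A fold against a group with no counts is a bound computed against a floor of 3 counts over the group.

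Alternatives were DESeq2 1.42.0 (Wald test, or likelihood ratio test for the interaction, over the same genes), DESeq2's size factors in edgeR, no low-count filter, a joint fit of 40 sections, a replicate block, spots with at least 1000 UMIs, leaving out the 25% of spots richest in smooth muscle genes, 2 bands per roll, the centre of the bounding box, the slide with both groups, and leaving out each section in turn. For single sections they were a pseudocount of 5 CPM, a minimum of 5 CPM, the SPF colon mean as baseline and TMM factors. An offset for GC content (last 500 bases of the longest transcript of at least 200 bases, GENCODE vM21; 31856 genes had a value) and fits of the interaction without sections that stood apart were added after seeing the data. Gene positions are from GENCODE vM21 on GRCm38, matched by Ensembl identifier. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

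Each step was tested on simulated data with 200 changed genes. With changes of 2-fold and 4-fold, 75% and 96% were recovered for GF against SPF in the colon (16906 genes), 59% and 90% in jejunum 1 (16365 genes), 71% and 95% for FMT against GF in the colon (16906 genes) and 72% and 91% for colon against ileum (16963 genes). Recovery was 37% and 79% for the interaction (17449 genes), 88% and 99% for the colon roll and 66% and 89% for its GF difference (15773 genes each). Between 4.1% and 7.9% of these calls were false. In the simulated GF colon comparison camera called the 1 shifted list and 0 of the others (16906 genes). For D12 against sham (32285 genes) the 4-fold rule found 200 of 200 genes changed 8-fold, and 94.6% of Poisson intervals covered the true value. Both simulated sections were Poisson draws from the sham proportions, the changed genes had at least 20 CPM, and the intervals were likewise tried on Poisson counts. This simulation held no spread between sections, so it checks the calculation and not the error between real sections.

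No cell types were assigned to spots and no deconvolution was run. Histology images were not used here.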

Results

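Spatial gene expression was measured in mouse intestine on fresh-frozen Swiss-roll sections with the 10x Visium assay, in which polyadenylated RNA is captured on barcoded spots and counted by unique molecular identifier (UMI). The 46 sections lay on 13 slides and came from wild-type mice. Each of 5 segments, namely duodenum, jejunum 1, jejunum 2, ileum and colon, was represented by 3 sections from SPF (specific-pathogen-free) mice, 3 from GF (germ-free) mice and 2 from FMT mice, which received a faecal microbiota transfer; these expansions are the usual ones and are not spelled out in the labels. A further 4 colon sections were from SPF mice of a DSS series (DSS, or dextran sulfate sodium, injures the colon epithelium), with 1 section each labelled sham, D12, D30 and D73. The last 2 sections were 1 SPF and 1 GF colon section tagged dark, a word the labels do not explain. A section held 1765 to 4639 tissue spots (median 3338) and 33926458 to 107883762 UMIs in total (median 58000344). The median UMI count per spot was between 9914 and 29859, and mitochondrial genes took 2.73% to 8.64% of the UMIs.

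Expression is given as CPM, the UMI counts of a whole section scaled to a total of 1000000, as mean ± SD over sections, and differences as log2 values ± SE. In tested comparisons the totals were adjusted by the TMM factors of that fit, so the level of a group can vary slightly between fits; values of the DSS and dark sections are unadjusted. The series design calls the sections of a group biological replicates, while no label names an animal, so p-values measure the spread between these sections. Among the 35 pairs of replicate sections, none agreed within counting noise (chi-square per degree of freedom 18.4 to 578). In the small intestine no slide held both SPF and GF sections, and the 3 sections of each group in a segment lay on 3 slides, so the spread within a group includes that between slides. SPF sections of the small intestine with the same replicate number shared a slide, and so did most GF sections there. FMT sections of the small intestine lay on slides that held no SPF or GF section. A batch common to the FMT slides can therefore not be told apart there from the transfer. In the colon 1 slide held 2 SPF and 2 GF sections. The section titled as the second FMT colon replicate carries a GF treatment tag, and it was placed with FMT by its title and by the number of FMT sections that the series design states.

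Along the SPF small intestine, part of the steady-state description that the series set out to make, the ileum was first set against the duodenum. Fabp6, the ileal bile acid-binding protein (ENSMUSG00000020405; chromosome 11, 43596049 to 43601540 in GRCm38), stood at 52750 ± 4024 CPM in the ileum and 1.43 ± 0.77 CPM in the duodenum (n = 3 sections each), a log2 difference of 15.15 ± 1.60. Slc10a2, the apical bile acid transporter, was higher in the ileum by 7.37 ± 0.53, and 6 of 7 bile acid uptake genes rose while 1 fell. Reg1, a secreted protein of the regenerating family (ENSMUSG00000059654; chromosome 6, 78422711 to 78428667), went the other way, at 7747 ± 2013 CPM in the duodenum and 5.57 ± 1.88 CPM in the ileum. Gata4, a transcription factor of the proximal small intestine, fell by 3.11 ± 0.15 from duodenum to ileum (adjusted p = 7.16e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

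Many genes of nutrient handling were lower in the ileum, although no list in this comparison passed camera with an estimated correlation. Of 19 lipid absorption genes, 15 fell and 1 rose; Fabp1, a fatty acid-binding protein, fell by 5.60 ± 0.41 and Apoa4, an apolipoprotein of chylomicrons, fell by 4.96 ± 0.27. All 11 carbohydrate genes fell, among them lactase (Lct), which fell by 3.21 ± 0.20, and the glucose transporter Slc2a2, which fell by 3.78 ± 0.19. In the iron and calcium group 10 of 12 fell; the iron exporter Slc40a1 fell by 4.36 ± 0.26 and the calcium-binding S100g fell by 8.01 ± 0.59. Of 22 xenobiotic metabolism genes 20 fell and 2 rose, with the cytochrome Cyp2b10 dropping by 4.72 ± 0.24, and 18 of 19 fatty acid oxidation genes fell. In the T cell and intraepithelial lymphocyte group 14 of 20 fell, including Gzma, a granzyme, which fell by 2.73 ± 0.74.

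In the ileum 18 of 19 Paneth cell genes rose. Defa24, an alpha-defensin, rose by 2.92 ± 0.34, a value that is uncertain because defensin genes share reads with near-identical copies. Among 25 epithelial antimicrobial genes 16 rose and 2 fell; Nos2, the inducible nitric oxide synthase, rose by 5.88 ± 0.70. Among 20 sterol biosynthesis genes 17 rose and 1 fell. Goblet cell genes (14 of 18 rose, 2 fell), smooth muscle genes (11 of 13 rose) and fibroblast genes (15 of 18 rose, 1 fell) were also higher. So were mesothelial genes (7 of 7 rose, median 2.43) and adipose genes (7 of 9 rose, 1 fell, median 6.01). Counts adjusted over the list alone were the same for these groups except for fatty acid oxidation (1 rose and 18 fell), smooth muscle (13 rose), adipose genes (8 rose) and fibroblasts (15 rose and 2 fell). The comparison called 9395 of 16963 genes (4366 higher and 5029 lower in the ileum), 3220 of them at least 2-fold; groups did not overlap for 63.7% of genes, where chance gives 10%. Of 41 lists, 19 passed camera with its preset correlation and 0 with an estimated one (adjusted p = 0.181 with an estimated correlation for the bile acid, lipid, xenobiotic, fatty acid and goblet lists, 0.185 for carbohydrate, 0.201 for iron and calcium, 0.301 for Paneth and antimicrobial, 0.343 for mesothelial genes, 0.353 for smooth muscle, 0.39 for fibroblasts, 0.407 for sterols and 0.615 for T cells and adipose genes).

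**Figure D1:**
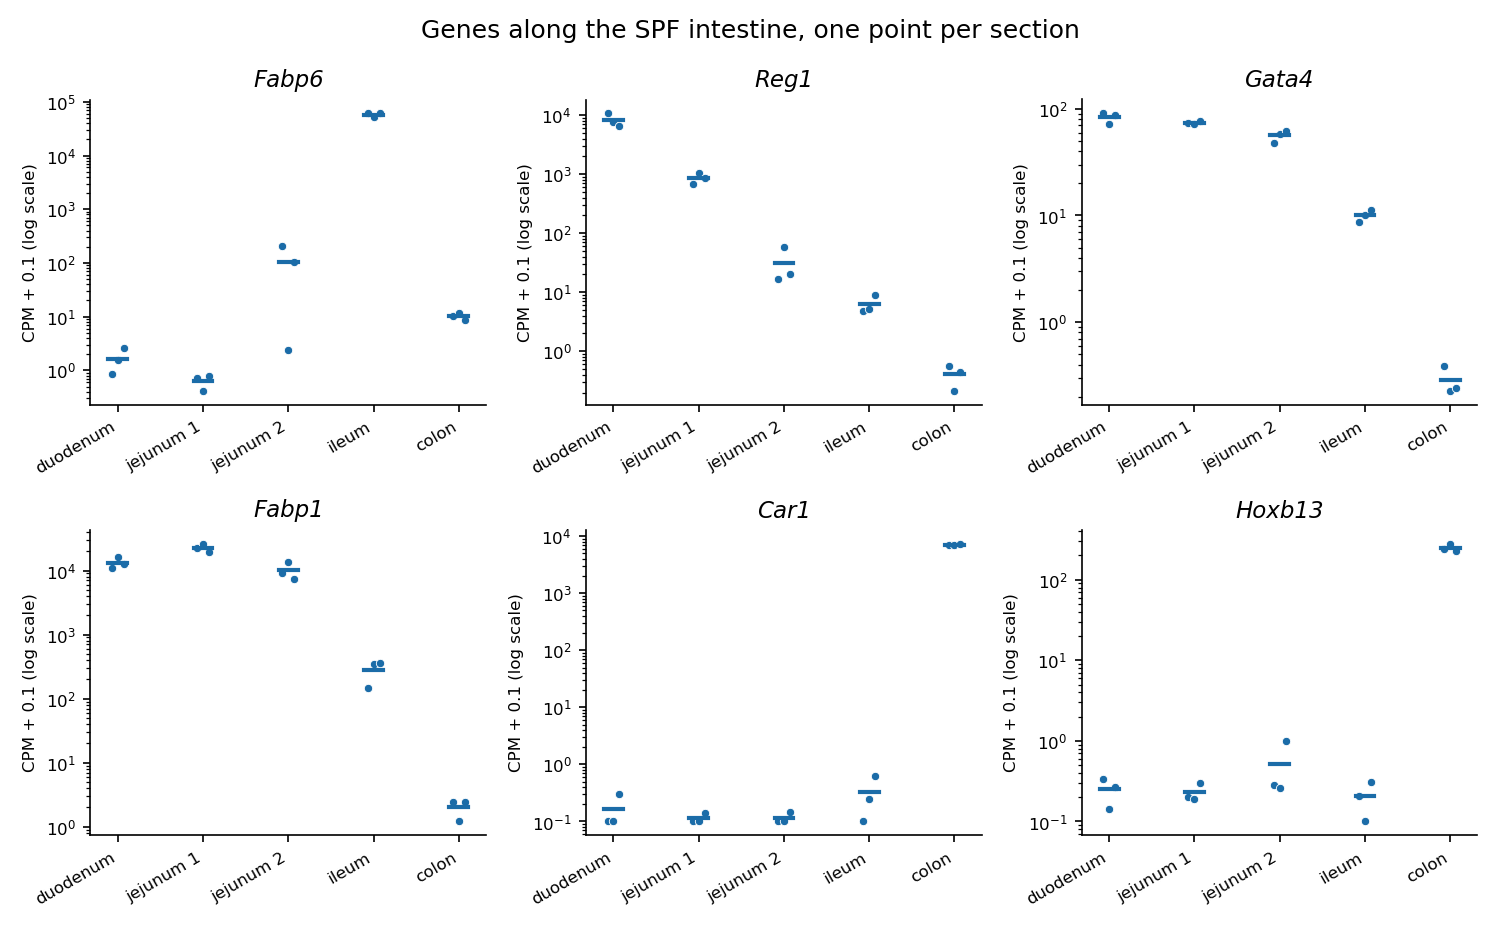
Expression of 6 genes in the 15 SPF sections of 5 segments, in CPM scaled with TMM factors over all 46 sections (log axis, offset by 0.1 CPM); each point is a section and each bar is the mean of 3. Fabp6 peaks in the ileum, Reg1 and Gata4 are highest in the duodenum and Fabp1 in jejunum 1, and Car1 and Hoxb13 lie far higher in the colon than in any other segment.

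The same axis was examined within the jejunum, between the parts labelled jejunum 2 and jejunum 1. Plb1, a brush-border phospholipase, rose by 9.32 ± 0.70 in jejunum 2 (270 ± 202 against 0.437 ± 0.17 CPM, n = 3 each) and Fabp6 rose by 7.57 ± 1.28. Pyy, the gut hormone peptide YY, rose by 3.61 ± 0.51. Reg1 fell by 4.71 ± 0.52 and Cyp1a1, a target of the aryl hydrocarbon receptor, fell by 3.15 ± 0.45 (edgeR's quasi-likelihood test, adjusted p = 0.00102). As groups, 13 of 19 fatty acid oxidation genes, 17 of 22 xenobiotic metabolism genes and 6 of 11 carbohydrate genes fell and none rose, while 9 of 19 macrophage genes rose and none fell. Adjusted over the list alone these became 16 fallen, 17 fallen and 1 risen, 8 fallen, and 10 risen. The comparison called 2123 of 16963 genes (1051 higher, 1072 lower), with 27.7% of genes not overlapping against 10% by chance. Of 41 lists 18 passed camera and 0 held (adjusted p = 0.0784 with an estimated correlation for fatty acid oxidation, 0.204 for xenobiotics, 0.332 for carbohydrates and macrophages). The count was 1344 without the second section of SPF jejunum 1 and 1272 without the first section of SPF jejunum 2.

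Colon and ileum of SPF mice were then compared. Car1, a carbonic anhydrase of colon epithelium (ENSMUSG00000027556; chromosome 3, 14766216 to 14808368), reached 6583 ± 179 CPM in the colon against 0.199 ± 0.24 CPM in the ileum (n = 3 each), and Aqp8, a water channel, rose by 13.53 ± 0.73. Hoxb13, a homeobox gene of the distal hindgut (ENSMUSG00000049604; chromosome 11, 96194316 to 96197447), stood at 228 ± 26.4 against 0.0959 ± 0.0945 CPM. Its paralogues Hoxa13 and Hoxd13, from other HOX clusters, were not counted in any ileum section and were at least 1120-fold and 610-fold higher in the colon (floor of 3 counts over the group). In the reverse direction Apoa1, an apolipoprotein, fell by 14.84 ± 0.50. Slc6a19, the neutral amino acid transporter (ENSMUSG00000021565; chromosome 13, 73679745 to 73704865), fell by 8.79 ± 0.17 (adjusted p = 8.63e-15, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

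All 13 peptide digestion genes, all 11 carbohydrate genes and all 7 bile acid uptake genes were lower in the colon, as were 15 of 19 lipid absorption genes (2 rose) and 16 of 19 Paneth genes (1 rose). Fgf15, the ileal hormone of bile acid feedback, was at least 1680-fold lower in the colon. Of 18 colon identity genes 16 rose and 1 fell, of 12 hindgut HOX genes 11 rose and 1 fell, and of 18 goblet genes 10 rose and 2 fell, with the mucin Muc2 up by 2.06 ± 0.14. All 18 neuron and glia genes, 16 of 18 fibroblast genes and 10 of 13 smooth muscle genes rose. Of immune genes 18 of 20 in the T cell, 13 of 20 in the interferon-gamma and 12 of 15 in the MHC class I list fell, lists that did not hold with an estimated correlation (adjusted p = 0.738, 0.421 and 0.421); the granzyme Gzma dropped by 4.33 ± 0.86 and the chemokine Cxcl9 by 3.58 ± 0.26. Adjusted over the list alone the counts were the same except for lipid absorption (16 fell), colon identity (2 fell) and Paneth cells (17 fell). The test called 9499 of 16963 genes (5024 higher, 4475 lower); 66.6% did not overlap, against 10% by chance. Of 41 lists 19 passed camera, and the peptide, lipid and colon identity lists held (adjusted p = 0.0269, 0.0343 and 0.00125 with an estimated correlation). The others named did not (adjusted p = 0.0788 with an estimated correlation for carbohydrates, 0.0802 for HOX, 0.0901 for bile acids, 0.217 for Paneth and goblet, 0.421 for neurons and glia, 0.445 for fibroblasts, 0.738 for smooth muscle).

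The effect of the microbiota was examined by setting GF against SPF sections in each segment. In the duodenum, transcripts of antibody-producing cells were lower in GF mice: Igha, the IgA heavy chain (ENSMUSG00000095079; chromosome 12, 113254830 to 113260236), was at 578 ± 89 CPM in GF and 4979 ± 931 CPM in SPF sections (n = 3 each), and Jchain, the joining chain of secreted IgA, fell by 3.45 ± 0.29. Of 17 plasma cell genes 11 fell, and of 15 B cell and follicle genes 8 fell. Ces2a, a carboxylesterase (ENSMUSG00000055730; chromosome 8, 104734003 to 104741634), fell by 2.38 ± 0.21, and Cyp2c55, a cytochrome P450 (ENSMUSG00000025002; chromosome 19, 39007019 to 39042693), fell by 1.93 ± 0.34; 4 of 22 xenobiotic metabolism genes fell. Mbl2, a mannose-binding lectin of innate immunity (ENSMUSG00000024863; chromosome 19, 30232942 to 30239687), rose by 4.08 ± 0.41, from 3.76 ± 1.14 to 63.6 ± 16.5 CPM (adjusted p = 0.00398, edgeR's quasi-likelihood test). The counts were 13 plasma cell genes and 15 B cell genes fallen, and 8 xenobiotic genes fallen and 1 risen, when adjusted over the list alone. The test called 270 of 16428 genes (55 higher, 215 lower in GF); 26.3% did not overlap, against 10% by chance, and 18 of 39 lists passed camera but 0 held (adjusted p = 0.432 with an estimated correlation for each list named). The count was 51 or 55 without SPF section 1 or 2, and 59, 73 or 68 without GF section 1, 2 or 3. DESeq2 called 676 genes and a joint fit of all 40 SPF, GF and FMT sections 429.

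In jejunum 1, Mbl2 rose by 5.01 ± 0.56, from 6.47 ± 3.63 CPM in SPF to 208 ± 56.2 CPM in GF sections (n = 3 each). Il1rl1, the IL-33 receptor (ENSMUSG00000026069; chromosome 1, 40429570 to 40465415), rose from 3.81 ± 0.421 to 11.4 ± 0.158 CPM. Of 20 T cell and intraepithelial lymphocyte genes 10 rose and none fell; the chemokine Ccl5 rose by 2.04 ± 0.33 and the granzyme Gzma by 1.65 ± 0.26. The mast cell proteases Mcpt1 and Mcpt2 rose by 2.93 ± 0.41 and 3.17 ± 0.45, values that are uncertain because these similar genes share reads. Of 22 xenobiotic metabolism genes 7 fell: Cyp1a1 fell by 3.18 ± 0.37, Cyp2c55 by 2.90 ± 0.31 and Ces2a by 2.67 ± 0.21 (adjusted p = 0.00138, edgeR's quasi-likelihood test). Of 16 plasma cell genes 6 fell, Igha by 1.80 ± 0.25, and of 19 fatty acid oxidation genes 3 fell, among them the peroxisomal thiolase Acaa1b, which fell by 1.29 ± 0.16. In the acute inflammation list 2 of 26 rose. Adjusted over the list alone these were 17 risen T cell genes, 16 fallen xenobiotic genes, 10 fallen plasma cell genes, 11 fallen fatty acid oxidation genes and 16 risen inflammation genes. The test called 175 of 16365 genes (82 higher, 93 lower); 19.9% did not overlap, against 10% by chance. Of 38 lists 22 passed camera. Acute inflammation and fatty acid oxidation held (adjusted p = 0.044 with an estimated correlation for both). Xenobiotics and plasma cells (adjusted p = 0.142 with an estimated correlation) and T cells (0.204) did not. Macrophage genes also took more of the UMIs in GF (0.0587% to 0.0712%) than in SPF sections (0.0323% to 0.0463%). MHC class II genes took 0.423%, 0.396% and 0.101% in GF sections 1, 2 and 3, against 0.0471% to 0.0903% in SPF sections. The count was 65, 63 or 102 without SPF section 1, 2 or 3 and 98 without the second GF section. DESeq2 called 711 and the joint fit 698.

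In jejunum 2, Mbl2 rose by 3.54 ± 0.49 and Il1rl1 by 1.14 ± 0.13 in GF sections (n = 3 each). Ces2a fell by 2.47 ± 0.25, from 421 ± 93.5 to 76.1 ± 18.9 CPM, Cyp2c55 by 2.15 ± 0.30, and the tight junction gene Cldn4 by 2.10 ± 0.30. Of 19 Paneth genes 3 rose, 18 adjusted over the list alone; Defa17, at 2002 ± 569 against 372 ± 39.5 CPM, shares reads with other defensins, and Ang4, an antimicrobial ribonuclease, differed by 3.13 ± 0.50 without passing (adjusted p = 0.0524, edgeR's quasi-likelihood test). Igha differed by -1.71 ± 0.33 (adjusted p = 0.0894, the same test). Of 22 xenobiotic genes 3 fell, 10 adjusted over the list alone. The test called 44 of 16181 genes (14 higher, 30 lower); 21% did not overlap, against 10% by chance, and 21 of 39 lists passed camera but 0 held (adjusted p = 0.279 with an estimated correlation for the Paneth and xenobiotic lists). By edgeR's test the count was 1, 0 or 6 without SPF section 1, 2 or 3 and 0, 0 or 20 without GF section 1, 2 or 3. The counts of 0 had 1130, 1412 and 1404 genes at an unadjusted p under 0.05. DESeq2 called 372, the joint fit 466 and edgeR without a low-count filter 102.

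In the ileum, Jchain fell by 2.52 ± 0.24 and Igha by 2.06 ± 0.27, from 5259 ± 912 to 1259 ± 191 CPM (n = 3 each); 4 of 17 plasma cell genes fell, 12 adjusted over the list alone. Cyp2c55 fell by 2.78 ± 0.32 and the cytochrome Cyp3a25 by 1.31 ± 0.18, in a xenobiotic list of which 2 of 21 fell, 7 adjusted over the list alone. Il1rl1 rose by 1.83 ± 0.25 (adjusted p = 0.0478, edgeR's quasi-likelihood test). The test called 20 of 16388 genes (3 higher, 17 lower); 27.6% did not overlap, against 10% by chance, and 12 of 40 lists passed camera but 0 held (adjusted p = 0.455 with an estimated correlation for plasma cells and xenobiotics). Sections stood apart here: the count was 944 without the second GF section, 125 without the third GF section, and 2, 6 or 9 without SPF section 1, 2 or 3. The 944 rests on GF sections 1 and 3. On the leading axis of deviations between replicate sections these scored 76.4 and 40.4, against -5.5 for GF section 2 and -3.0 to 5.4 for SPF. DESeq2 called 788, the joint fit 1151 and edgeR without a low-count filter 43.

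In the colon, Cyp2c55 fell by 3.37 ± 0.21, from 2903 ± 186 CPM in SPF to 282 ± 55.8 CPM in GF sections (n = 3 each), Ces2a by 2.85 ± 0.16 and the drug efflux pump Abcb1a by 1.65 ± 0.18. Of 21 xenobiotic metabolism genes 8 fell. S100g, a calcium-binding protein of absorptive cells (ENSMUSG00000040808; chromosome X, 162961992 to 162964599), fell by 5.50 ± 0.56, and 4 of 12 iron and calcium genes fell. Slc6a19 rose by 2.47 ± 0.17, from 1.40 ± 0.18 to 7.81 ± 1.06 CPM, and the cystine transporter subunit Slc7a9 by 1.86 ± 0.16, and 4 of 13 genes of peptide digestion and uptake rose, a list that did not hold with an estimated correlation (adjusted p = 0.054). Cck, the hormone cholecystokinin, rose by 3.32 ± 0.46 (adjusted p = 0.0225, edgeR's quasi-likelihood test). Saa1, an acute-phase serum amyloid whose copies share reads (ENSMUSG00000074115; chromosome 7, 46740497 to 46742980), rose from 2818 ± 203 to 7735 ± 1482 CPM.

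Immune genes of the colon moved in both directions. Igha fell by 1.77 ± 0.37 and Jchain by 1.75 ± 0.31, with 2 of 17 plasma cell genes falling and 1 rising. That riser was Ighg1, an IgG heavy chain, which rose by 1.55 ± 0.20. Of 20 interferon-gamma genes 4 rose, such as the GTPase Iigp1, which rose by 1.21 ± 0.27, and 1 of 14 B cell genes rose. Adjusted over the list alone, 11 xenobiotic genes fell and 2 rose, 6 iron and calcium genes fell, 9 peptide genes rose, 6 plasma cell genes fell and 1 rose, 16 interferon-gamma genes rose and 14 B cell genes rose. The test called 570 of 16906 genes (338 higher, 232 lower); 24% did not overlap, against 10% by chance, and 17 of 42 lists passed camera but 0 held (adjusted p = 0.269 with an estimated correlation for xenobiotics, 0.331 for interferon-gamma, 0.365 for B cells and for iron and calcium, 0.475 for plasma cells). On the slide with both groups (2 against 2 sections) 987 genes were called, 712 higher and 275 lower. The count was 119 or 132 without SPF section 1 or 2 and 245 without the second GF section; DESeq2 called 1271 and the joint fit 335.

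**Figure D2:**
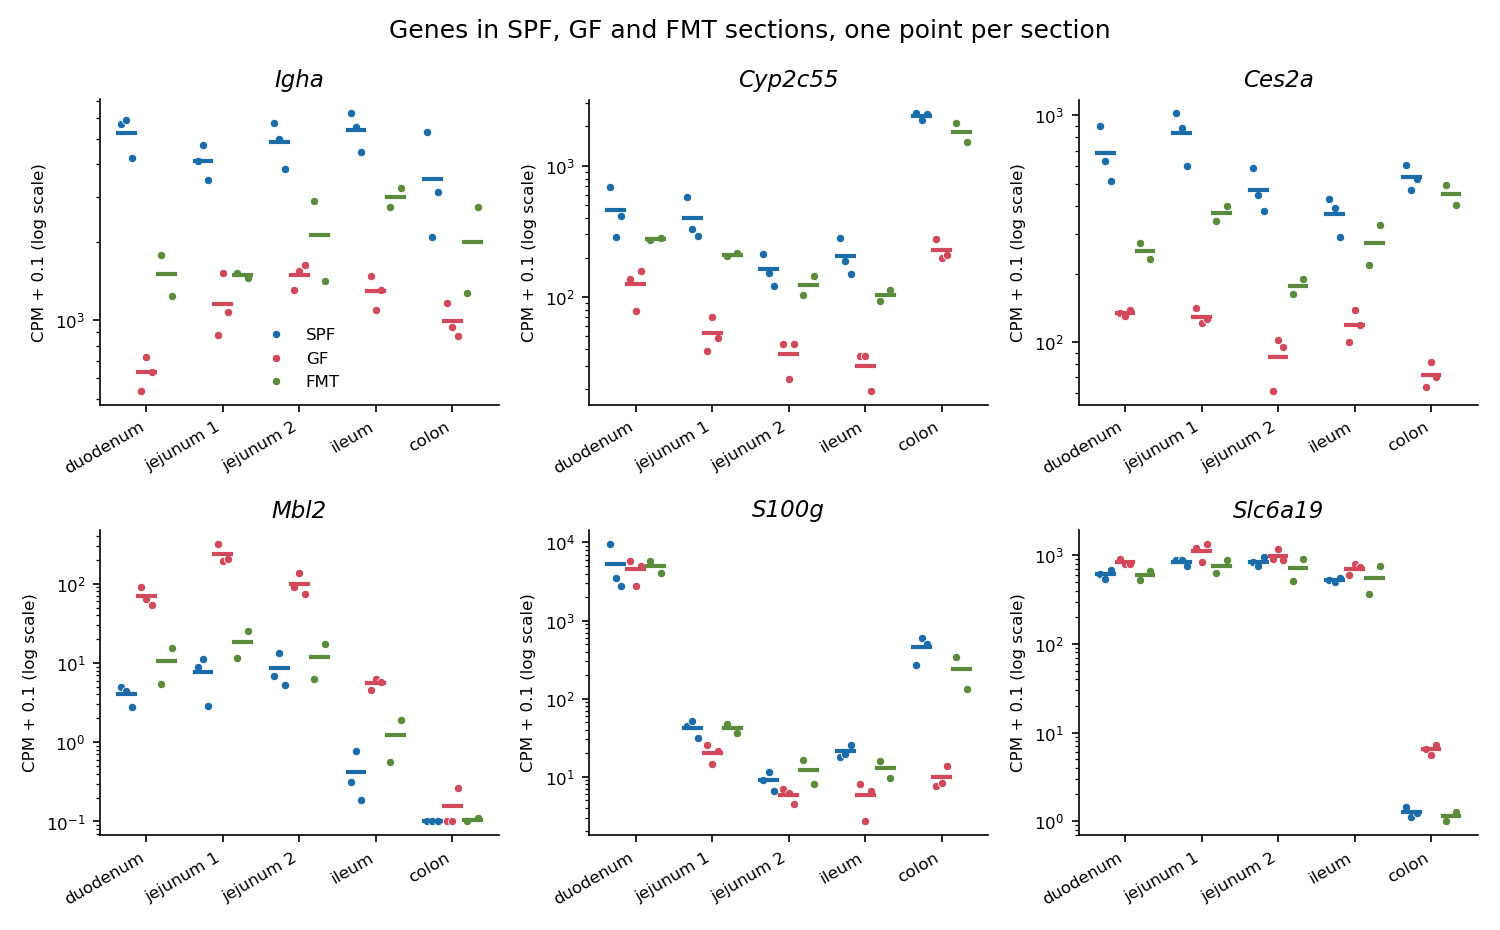
Expression of 6 genes in the 40 sections of SPF, GF and FMT mice by segment, in CPM scaled with TMM factors over all 46 sections (log axis, offset by 0.1 CPM); each point is a section and each bar a group mean. Igha stands at 3460 to 6275 CPM in the SPF and 534 to 1637 CPM in the GF small intestine, and S100g and Slc6a19 separate GF from SPF most in the colon.

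Whether the GF effect differed between segments was tested as an interaction over the 30 SPF and GF sections. Slc6a19 was higher in the GF colon by 2.43 ± 0.18 and by 0.20 to 0.44 in the other segments (interaction adjusted p = 3.70e-05, edgeR's quasi-likelihood test). Cck gave 3.27 ± 0.47 in the colon. Ggt1, gamma-glutamyltransferase, gave -3.55 in the colon and lay between -0.38 and 0.18 elsewhere. S100g gave -0.26 in the duodenum, -1.85 in the ileum and -5.54 ± 0.52 in the colon. Saa1 differed by 1.41 ± 0.37 in the colon and -1.81 in the ileum. Tmigd1, an adhesion protein of epithelial cells, gave 2.12 in the duodenum and -0.42 in the ileum. The interaction called 512 of 17449 genes, 43 of them with 2-fold or larger effects in opposite directions. Without replicate 1, 2 or 3 of every group the count was 32, 29 or 162, without the second GF ileum section 974, and without that section and the first GF colon section 1092. DESeq2's likelihood ratio test called 1690, edgeR without a low-count filter 332 and edgeR with the replicate number as a block nested in status 1543.

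As a further test of regulation by the microbiota, FMT sections were set against GF sections. In jejunum 1, Mbl2 fell by 3.72 ± 0.63 in FMT and Il1rl1 fell by 2.69 ± 0.16 (1.76 ± 0.124 against 11.4 ± 0.158 CPM; n = 2 FMT and 3 GF sections). Cyp1a1 rose by 3.09 ± 0.39 (adjusted p = 0.0182, edgeR's quasi-likelihood test), Cyp2c55 by 1.97 ± 0.32 and Ces2a by 1.49 ± 0.22, with 5 of 22 xenobiotic genes and 5 of 19 fatty acid oxidation genes rising. In the acute inflammation list 1 of 26 fell. Adjusted over the list alone, 11 xenobiotic genes rose and 1 fell, 13 fatty acid oxidation genes rose and 9 inflammation genes fell. The test called 119 of 16365 genes (65 higher, 54 lower in FMT); 28.6% did not overlap, against 20% by chance. Of 38 lists 22 passed camera; fatty acid oxidation and acute inflammation held (adjusted p = 0.0431 and 0.0494 with an estimated correlation), and xenobiotics did not (0.289). The count was 11 or 15 without FMT section 1 or 2 and 207 or 27 without GF section 1 or 2; DESeq2 called 514, the joint fit 555 and edgeR without a low-count filter 189.

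In the colon, FMT sections had more S100g than GF sections, by 4.57 ± 0.55, more Cyp2c55 (2173 ± 521 against 282 ± 55.8 CPM, a rise of 2.95 ± 0.22) and more Ces2a, by 2.60 ± 0.16 (n = 2 and 3). Slc6a19 fell by 2.64 ± 0.20 and Slc7a9 by 2.08 ± 0.18 (adjusted p = 0.000757, edgeR's quasi-likelihood test). Saa1 fell by 1.26 ± 0.22, to 3231 ± 69.5 CPM. Ang4, at 2306 ± 2230 against 112 ± 41.7 CPM, did not pass (adjusted p = 0.104, the same test). Of 21 xenobiotic genes 5 rose and of 13 peptide digestion genes 4 fell; adjusted over the list alone 7 rose and 4 fell, and 6 fell. The test called 221 of 16906 genes (118 higher, 103 lower); 33.8% did not overlap, against 20% by chance, and 16 of 42 lists passed camera but 0 held (adjusted p = 0.118 with an estimated correlation for peptides, 0.696 for xenobiotics). The count was 2421, 64 or 91 without GF section 1, 2 or 3 and 29 or 49 without FMT section 1 or 2; DESeq2 called 940 and edgeR without a low-count filter 364.

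In the remaining segments few genes were called between FMT and GF. In jejunum 2 there were 6 of 16181, among them Il1rl1, which fell by 2.03 ± 0.16 in FMT, and Acaa1b, higher by 2.11 ± 0.25 (adjusted p = 0.041, edgeR's quasi-likelihood test). That count was 24 or 0 without FMT section 1 or 2 (1216 genes at an unadjusted p under 0.05 behind the 0), 2, 3 or 2 without GF section 1, 2 or 3, 134 by DESeq2, 125 in the joint fit and 20 without a low-count filter. In the duodenum and ileum edgeR called 0, with 1628 and 1288 genes at an unadjusted p under 0.05. DESeq2 called 156 and 112 there, the joint fit 79 and 48. Non-overlapping genes made up 23.4% in the duodenum, 18.3% in jejunum 2 and 20.8% in the ileum, against 20% by chance, and 15 of 39, 18 of 39 and 16 of 40 lists passed camera with its preset correlation, but 0 with an estimated one. Il1rl1 differed by -2.08 ± 0.29 in the ileum and did not pass (adjusted p = 0.131, edgeR). Without the first FMT duodenum section 76 genes were called, without the second GF ileum section 18 and without the first FMT ileum section 1.

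Against SPF, FMT sections of the duodenum had fewer transcripts of B and plasma cells. The B cell receptor component Cd79b fell by 3.36 ± 0.45 and Igha by 1.82 ± 0.28, from 4979 ± 931 to 1407 ± 354 CPM (adjusted p = 0.0371, edgeR's quasi-likelihood test; n = 2 FMT and 3 SPF sections). Of 15 B cell genes 7 fell and of 17 plasma cell genes 5 fell, 15 and 13 adjusted over the list alone (adjusted p = 0.303 with an estimated correlation for both). The B cell list varied widely between sections of some other groups, such as 0.00119% to 0.00914% of UMIs in SPF jejunum 1. The test called 52 of 16428 genes there (2 higher, 50 lower), with 23.5% not overlapping against 20% by chance. That share was larger where fewer genes were called, at 28.5% in jejunum 1, 27.6% in jejunum 2, 42.2% in the ileum and 41.7% in the colon. On the leading axis of deviations between replicate sections, FMT sections of the ileum scored 13.4 and 27.1, and SPF sections -3.0 to 5.4. In the colon FMT sections scored 22.8 and 31.7, and SPF sections -2.7 to 3.3. In the other segments the ranges of FMT and SPF scores overlapped. How far this axis accounts for the shares was not tested. From duodenum to colon 16 of 39, 13 of 38, 17 of 39, 19 of 40 and 10 of 42 lists passed camera and 0 held. There was 1 call in jejunum 2, and 1 predicted gene was called in the ileum, while DESeq2 called 250 and 183 and the joint fit 219 and 138. In jejunum 1 and the colon edgeR called 0, with 1007 and 3155 genes at an unadjusted p under 0.05, while DESeq2 called 90 and 540. The duodenal count was 1, 0 or 90 without SPF section 1, 2 or 3 and 0 or 1 without FMT section 1 or 2 (896 and 2787 genes at an unadjusted p under 0.05 behind the zeros). It was 249 by DESeq2, 82 in the joint fit and 27 with an offset for GC content. The colon count was 190 with a replicate block, 123 without the third SPF section and 1 without the first FMT section. The jejunum 2 count was 33 or 3 without FMT section 2 or 1 and 0 without any 1 SPF section (1325, 1166 and 918 genes at an unadjusted p under 0.05). The ileum count was 0 without SPF section 1 or 3 or either FMT section (889, 953, 1713 and 676 genes at an unadjusted p under 0.05).

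Genes called between GF and SPF were often called in the reverse direction between FMT and GF. In jejunum 1, 28 of 82 genes higher in GF were lower in FMT and 36 of 93 genes lower in GF were higher in FMT, where independent lists would share 0.271 and 0.369. In the colon the overlaps were 58 of 338 and 76 of 232, against 2.06 and 1.62 for independent lists. None were called in the same direction. Both comparisons use the same 3 GF sections. In 20 simulations the SPF, GF and FMT sections were all drawn from 1 common mean per gene. The mean overlap was then 0.15 (highest 2) in jejunum 1 and 0 in the colon. With no group differing, few genes are called at all, so these overlaps cannot show how many reversed calls come from sharing the GF sections. Across genes, which are not independent replicates, the log2 differences had a correlation of -0.65 in jejunum 1 (-0.43 simulated) and -0.54 in the colon (-0.46 simulated). The covariances were -0.161 (-0.046 simulated) and -0.129 (-0.034 simulated). With 3 GF sections the controls could not be divided, so part of the excess may come from sharing them.

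Within the rolls, expression was compared between the outer and inner band of spots, each with 1 in 3 of a section's spots by distance from the centre, with the section as a block. The labels do not state which end of the gut lay outside. In the colon (8 SPF, GF and FMT sections), Reg3b, an antimicrobial lectin whose family members share reads, was at 324 ± 207 CPM in the outer and 4.53 ± 2.26 CPM in the inner band, a rise of 6.02 ± 0.21 with the same direction in 8 of 8 sections. The bile acid exporter subunit Slc51a rose by 5.36 ± 0.12 and Osr2, an odd-skipped transcription factor, by 5.26 ± 0.13. In the inner band Hoxd13 was higher, at 39.1 ± 11.3 against 1.06 ± 0.588 CPM (adjusted p = 4.13e-10, edgeR's quasi-likelihood test), and Fxyd4, a sodium pump regulator, fell by 4.48 ± 0.17 toward the outer band. Of 20 xenobiotic genes 15 were higher and 1 lower outside, of 18 fatty acid oxidation genes 15 and 1, and of 20 proliferation genes 16 and 0. Macrophage (16 of 19), smooth muscle (12 of 13) and fibroblast genes (15 of 18, with 1 opposite) were lower outside. The test called 8674 of 15773 genes (4297 higher, 4377 lower outside). Of 41 lists 13 passed camera and 0 held (adjusted p = 0.401 with an estimated correlation for xenobiotics and fibroblasts, 0.406 for macrophages, 0.559 for fatty acid oxidation, 0.589 for smooth muscle, 0.652 for proliferation).

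The outer-inner difference of the colon was itself compared between GF and SPF. Cyp2c55 was 3.34 ± 0.0375 log2 units higher outside in GF and 1.80 ± 0.213 in SPF sections (mean ± SD, n = 3 each), a difference of 1.55 ± 0.13 (adjusted p = 1.38e-05, edgeR's quasi-likelihood test). Cck had ratios of 3.17 ± 0.391 and 0.80 ± 0.268. Ggt1 went the other way, with 0.57 ± 0.191 in GF and 3.86 ± 0.492 in SPF, as did Slc7a9 with -0.98 ± 0.492 and 1.31 ± 0.446. Of 15 MHC class I genes 4 had a lower outer-inner ratio in GF, 5 adjusted over the list alone; H2-Q1 differed by -1.21 ± 0.13. The test called 265 of 15773 genes (99 higher, 166 lower in GF); 14 of 41 lists passed camera and 0 held (adjusted p = 0.452 with an estimated correlation for MHC class I). The count was 165, 157 or 121 without SPF section 1, 2 or 3 and 128 without the first GF section.

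In the ileum roll, lactase rose by 4.63 ± 0.46 in the outer band (617 ± 245 against 51.5 ± 90.5 CPM, 8 sections), Fabp1 by 3.31 ± 0.28 and Apoa4 by 3.22 ± 0.38. Slc10a2 fell by 2.17 ± 0.15 from the inner to the outer band, Fabp6 by 1.71 ± 0.12, and Hoxb9, a homeobox gene, by 3.73 ± 0.17 (adjusted p = 2.51e-07, edgeR's quasi-likelihood test). In the outer band 17 of 19 lipid absorption genes, 19 of 20 T cell genes, 15 of 15 MHC class I genes and 15 of 20 interferon-gamma genes were higher with 0 lower, and 15 of 20 sterol genes were lower with 1 higher and 8 of 9 adipose genes with 0 higher. With p adjusted over the list alone, 17 lipid genes rose and 1 fell, 17 interferon-gamma genes rose and 16 sterol genes fell. The test called 4715 of 15118 genes (2473 higher, 2242 lower outside); 20 of 39 lists passed camera and 0 held (adjusted p = 0.299 with an estimated correlation for each list named). Between GF and SPF the outer-inner difference passed for 6 genes: the MHC class II genes H2-Aa (a difference of 1.88 ± 0.25), H2-Ab1 (1.62 ± 0.20) and H2-Eb1 (1.49 ± 0.20), and Sprr1a, S100g and Plaat3 (adjusted p = 0.0314 for H2-Aa, edgeR's quasi-likelihood test). For it 15 of 39 lists passed camera and 0 held. The roll count was 7141 without the second GF section and 2563 or 2933 without FMT section 1 or 2. The difference count was 2190 without the second GF section, 3 or 0 without GF section 1 or 3 and 0 without SPF section 1 or 2 (615, 648 and 647 genes at an unadjusted p under 0.05 behind the zeros); with 2 bands per roll, or another centre, it was 0 (886 and 856), without a low-count filter 11, and DESeq2 called 16.

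The DSS series, made to follow inflammation of the colon and recovery from it, has 1 section per label, so no test was possible. Values are given with exact Poisson 95% intervals that cover counting error only, and genes by a rule of at least 4-fold with 20 CPM or more in the higher section. At D12, genes of neutrophils and acute inflammation stood far above the sham section. S100a9, a neutrophil calprotectin subunit (ENSMUSG00000056071; chromosome 3, 90692632 to 90695721), was at 635 CPM (628 to 643) against 0.339 CPM (0.189 to 0.558) in sham and a mean of 0.469 CPM in SPF colon. Il1b, the cytokine interleukin-1 beta, was at 365 CPM (359 to 371) against 1.90 CPM (1.51 to 2.35), and Saa3, an acute-phase amyloid, at 1151 against 10.0 CPM. Ly6a, a surface marker of regenerating epithelium, was 6.36-fold and Lcn2, the antibacterial lipocalin, 47.9-fold higher. Mptx1, a mucosal pentraxin, was at 6.21 against 2498 CPM, Ang4 at 12.9 against 284 CPM and Igha at 1411 against 5041 CPM. The median log2 ratio was 4.68 over the acute inflammation list, in which 28 of 32 genes passed the 4-fold rule, 3.50 over neutrophils, 2.02 over interferon-gamma and 1.67 over epithelial repair, each at the 100th percentile of 10000 matched random lists. The plasma cell list stood at -1.32, at percentile 0. By the same method SPF colon sections 1 to 3 against sham gave -0.479 to -0.266 for acute inflammation, -1.06 to -0.944 for interferon-gamma, -0.196 to -0.162 for epithelial repair and -0.752 to 0.155 for plasma cells, at percentiles of 0 to 92.77, so a percentile does not cover the spread between sections. By the 4-fold rule 125 genes were higher and 18 lower, of which 125 and 15 lay beyond all 3 SPF colon sections. With SPF colon as the baseline 216 genes passed, and with a minimum of 5 CPM 260.

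At D30 the inflammatory genes were lower than at D12 and partly above sham: S100a9 was at 8.33 CPM and Il1b at 8.43 CPM. Clu, a marker of regenerating epithelium, was instead higher at D30 than at D12, at 140 against 46.9 CPM, with 34.1 CPM in sham. Il1rl1 stood at 23.7 against 1.42 CPM and the nuclear RNA Malat1 at 1114 against 164 CPM, while Fxyd4 was at 15.9 against 187 CPM. The nuclear RNA Kcnq1ot1 (31.9 against 2.12 CPM) and mitochondrial mt-Nd3 (1888 against 358 CPM) were higher as well, and Rpl35, a ribosomal protein gene, lower (121 against 910 CPM). Mitochondrial genes took 7.11% of UMIs at D30 and 7.48% at D73, on 1 slide, against 3.54% in sham and 3.42% at D12, on another, and 5.67% to 6.86% in SPF colon. B cell genes took 0.0132% of UMIs at D12, 0.0161% at D30, 0.0109% at D73, 0.00268% in sham and 0.00214% to 0.0026% in SPF colon. GF colon sections ranged from 0.00481% to 0.0173%, so this list varied widely between sections. List medians were 1.13 for acute inflammation and 1.98 for B cells (both at percentile 100) and -0.85 for type I interferon genes (percentile 0). Sham was itself high in the last of these: type I interferon genes took 0.109% of its UMIs, 0.0418% to 0.0460% in SPF colon, 0.0633% at D30 and 0.0386% at D73, so the share at D30 lay below sham and above SPF colon. SPF colon sections against sham had medians of -1.63 to -1.19 for this list, also at percentile 0. The rule gave 18 genes higher and 22 lower (16 and 13 beyond all 3 SPF colon sections), or 9 and 29 with TMM factors, which move the split; 78 genes passed with a minimum of 5 CPM and 26 with a pseudocount of 5 CPM. At D73, S100a9 was at 2.91 CPM and Il1b at 2.31 CPM. Car1 was at 3390 CPM, against 7243 CPM in sham and 7968 to 8694 CPM in SPF colon. Mptx1 was at 910 CPM, against 2498 CPM in sham and 2808 to 5377 CPM in SPF colon. Lcn2, Reg3b and Ly6a lay within the range of SPF colon. Ighg1 stood at 51.6 against 4.65 CPM in sham and 26.0 to 35.2 CPM in SPF colon, and Igha at 7394 against 5041 CPM and 2351 to 6186 CPM. Dbp, a clock output gene, was at 12.9 against 241 CPM in sham and 44.2 to 117 CPM in SPF colon. Medians were 1.59 for B cells (percentile 100), 0.49 for plasma cells (percentile 99.98, while SPF colon sections against each other gave -0.746 to 0.663) and, against the high sham section, -1.79 for type I interferon genes (percentile 0). The rule gave 4 genes higher and 65 lower, of which 3 and 16 lay beyond all 3 SPF colon sections, 12 in all with SPF colon as the baseline and 44 with a pseudocount of 5 CPM. As background, SPF colon sections 1, 2 and 3 themselves differed from sham by 84, 82 and 50 genes. D12 and sham shared a slide and D30 and D73 another, and the median log2 ratio over all genes at the minimum level was 0.18 at D12, 0.25 at D30 and 0.04 at D73; TMM factors shift the ratios by -0.17, -0.24 and -0.03.

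**Figure D3:**
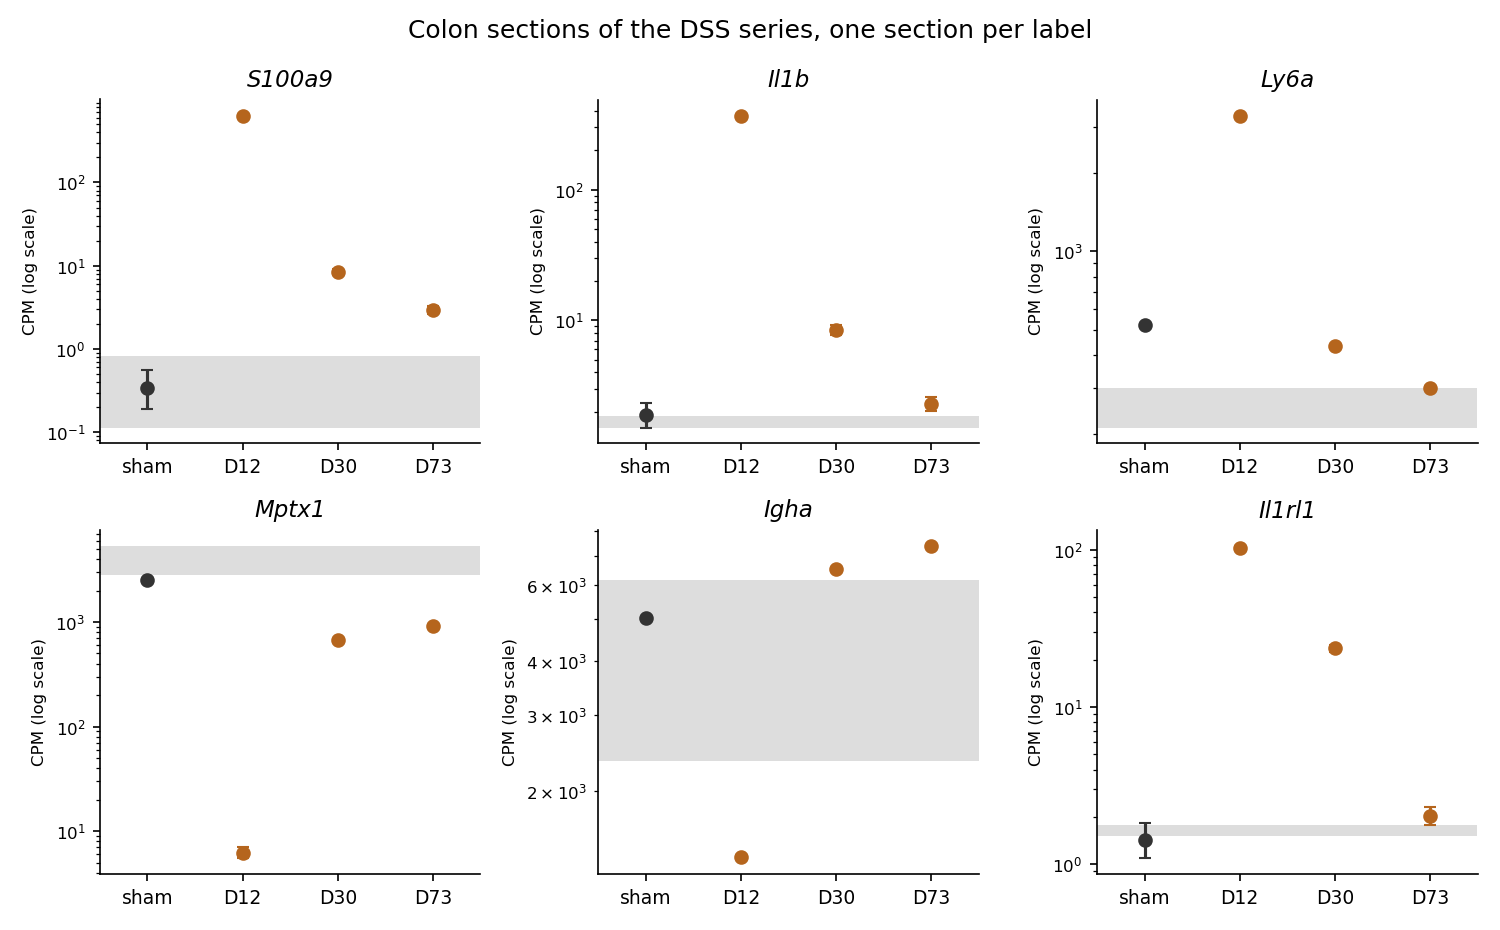
Expression of 6 genes in the sham, D12, D30 and D73 colon sections, in CPM of the whole section (log axis), with exact Poisson 95% intervals; the grey band spans SPF colon sections 1 to 3. S100a9 and Il1b peak at D12, at 635 and 365 CPM, and Mptx1 falls to 6.21 CPM there.

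The dark sections were compared with the other colon sections of the same status for the circadian clock list; with 1 dark section of each status no test was run. Per2, a core repressor of the clock (ENSMUSG00000055866; chromosome 1, 91415982 to 91459324), was at 36.4 CPM in the SPF and 26.4 CPM in the GF dark section, against 6.33 ± 3.78 and 5.99 ± 1.91 CPM in the other sections (n = 3 each). Cry1, another repressor, was at 28.4 and 31.1 CPM against 8.93 ± 0.734 and 9.88 ± 4.73 CPM. Nr1d1, the receptor REV-ERB alpha, was at 15 and 3.01 CPM against 80.0 ± 12.2 and 53.7 ± 18.6 CPM, and Dbp at 23.4 and 7.68 CPM against 74.9 ± 37.6 and 58.8 ± 51.7 CPM. Each of these 4 genes lay beyond all 3 other sections in both dark sections. The list median was 0.294 in SPF (percentile 97.5 of 10000 matched lists) and 0.182 in GF (percentile 99.7), over members that went both ways. Taken against single sections it ranged from 0.123 (percentile 29.75) to 0.742 in SPF and from -0.135 to 0.9 in GF. Sections without the tag, each compared with the others of its status, gave -0.563 to 0.501 in SPF and -0.855 to 0.721 in GF, at percentiles from 0 to 100.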

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

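Tests of the GC content and of the axis of deviations between libraries were set out before their own results were seen, with the GC offset added after the comparisons had been run; the other splits of the sections and both tests of roll orientation were chosen after the results were seen. Groups held at most 3 sections, too few for a test of single sections far from the others.

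The GF effect differed between segments for 512 genes. Slc6a19 (adjusted p = 3.70e-05), Slc7a9 (1.93e-05) and Cck (0.00652) stood out in the colon, all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. So did Ggt1 (1.85e-06) and S100g (0.000241), which were lower there. By the same test Saa1 (0.0151), Tmigd1 (0.00372), the cytochrome Cyp3a25 (0.000202), Jchain (0.0339) and Cldn4 (0.0403) also differed. Of 100 splits of the sections into SPF and GF within segments, the real one included, 1 gave as many genes. The highest of the others gave 192. These splits also break up the mean GF effect over segments, which was called for 3353 genes. They therefore do not test a difference between segments alone. They also take segments as independent, while same-numbered SPF and most same-numbered GF sections of the small intestine shared a slide. For these reasons they cannot exclude chance for the differences between segments. With the replicate number as a block nested in status the count was 1543.

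The difference between outer and inner colon spots differed between GF and SPF for 265 genes, with a log2 difference of 1.55 for Cyp2c55, 2.28 for Cck, -3.35 for Ggt1, -2.45 for Slc7a9 and -1.21 for H2-Q1. In the ileum it differed for 6 genes: 1.88 for H2-Aa, 1.62 for H2-Ab1, 1.49 for H2-Eb1, 1.60 for Sprr1a, 1.14 for S100g and 1.13 for Plaat3. The 10 splits of 3 GF and 3 SPF sections are too few for a share under 0.05; 1 split, the real one, gave as many genes in each, and the highest of the others gave 3 in the colon and 0 in the ileum.

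Genes called between GF and SPF were weighed against technical explanations in each segment. An offset for GC content left the log2 differences of called genes in place, at a median ratio of corrected to uncorrected of 1.01 in the duodenum, 0.995 in jejunum 1, 0.995 in jejunum 2, 1.02 in the ileum and 0.999 in the colon, which argues against GC content as the cause. The leading axis of deviations between replicate sections was learnt on the other segments. It predicted a median share of 0.004, -0.001, 0.0, 0.031 and 0.028 of those differences. Genes that spread along it within groups are less likely to be called, so a low share among called genes cannot decide the question. Mean GF and SPF scores on it differed little in the duodenum, jejunum 1 and jejunum 2 (1.8, 1.5 and 0.9). They differed more in the ileum (37.1, with GF sections at -5.5 to 76.4 and SPF sections at -3.0 to 5.4). In the colon they differed by 13.4 (GF sections at 2.3 to 29, SPF sections at -2.7 to 3.3). In the small intestine no slide held both groups, but each group of a segment lay on 3 slides, so differences between single slides are part of the spread that the test uses; a batch common to all slides of a group is named by no label and was not tested. In the colon the slide with both called 987 genes. Microbial status, the difference that the design names, stays open and may account for the calls.

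Other splits of 3 GF and 3 SPF sections are 10 per segment, too few for a share under 0.05. The real split called 270 genes in the duodenum (1 split as large, highest other 4), 175 in jejunum 1 (1, highest other 0), 44 in jejunum 2 (1, highest other 0) and 570 in the colon (1, highest other 0). In the ileum 2 splits gave at least the 20 genes of the real one, and the split with SPF sections 1 and 2 beside GF section 2 gave 109, which points to a structure among these sections other than their group. That split follows the scores on the axis of deviations between replicate sections. GF sections 1 and 3 and SPF section 3 scored 76.4, 40.4 and 5.4. GF section 2 and SPF sections 1 and 2 scored -5.5, -3.0 and -2.4. The 3 GF sections lay on different slides, and the cause was not tested. The limit of 10 splits holds for the SPF segments too. The real split gave 9395 genes for ileum against duodenum (1 split as large, highest other 0). It gave 2123 for jejunum 2 against jejunum 1 (1, highest other 80) and 9499 for colon against ileum (1, highest other 0).

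Outer and inner spots differed for 8674 genes in the colon and 4715 in the ileum. Of 40 exchanges of outer and inner within sections, 1, the real one, gave as many in each, with 1709 and 248 as the highest of the others. Chance is therefore unlikely, although a share under 1 in 40 could not be reached. The labels do not give the orientation of the rolls. Of 3613 genes called both along the ileum roll and between ileum and duodenum, 91.4% placed the outer spots nearer the duodenal end, and of 5465 genes called both along the colon roll and between colon and ileum, 65.1% placed the outer spots nearer the ileal end. A candidate explanation is that the rolls were wound with the proximal end outside. Distance from the centre also follows the amount of muscle and the folding of the roll, which stay open for the colon and the ileum. In most ileum sections the smooth muscle list took more of the UMIs in the inner band, such as 0.669% against 0.333% in GF section 1. FMT section 2 had 0.45% inside and 0.462% outside. Smooth muscle genes were also higher in the ileum than in the duodenum, so the 91.4% cannot separate orientation from muscle.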

How the results depend on the processing

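Alternatives were planned except the offset for GC content and the fits of the interaction without GF ileum section 2 or GF colon section 1, which were chosen after seeing the data. A count of genes is said to be kept when it lies within 1.5 times its reported value. The cause of a move was not tested, except that leaving out sections, spots or genes changes what enters the test. Kept throughout were all 23 counts with DESeq2's size factors in edgeR and all 8 with only spots of at least 1000 UMIs. Named genes with a test (120 genes and comparisons) gave 725 values with sections left out, of which 562 kept their call, 162 lost it and 1 gained one; under the other alternatives 747 of 814 values kept it, 58 lost it and 9 gained one, and none of these values changed sign. Of 66 values of DSS genes, 22 moved by less than counting error and 44 by more, with 0 changes of sign. At 33926458 UMIs or more per section, depth limits genes near the floor of 3 counts. Over all genes replicate sections differed by more than counting noise (chi-square per degree of freedom 18.4 to 578). How far the number of sections limits the counts was not tested.

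DESeq2's Wald test kept 6 of 22 counts. For GF against SPF it called 676 genes in the duodenum, 711 in jejunum 1, 372 in jejunum 2, 788 in the ileum and 1271 in the colon. In the same order of segments it called 156, 514, 134, 112 and 940 for FMT against GF and 249, 90, 250, 183 and 540 for FMT against SPF. It called 16 for the outer-inner difference of the ileum between GF and SPF, and its likelihood ratio test 1690 for the interaction. The joint fit of 40 sections kept 1 of 15. It called 429, 698, 466, 1151 and 335 genes for GF against SPF in that order, 79, 555, 125 and 48 for FMT against GF in the first 4 segments, and 82, 14, 219, 138 and 3 for FMT against SPF.

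Without a low-count filter 11 of 23 counts were kept. FMT against GF gave 2 in the duodenum, 189 in jejunum 1, 20 in jejunum 2 and 364 in the colon, and FMT against SPF gave 6 in jejunum 1, 2 in jejunum 2, 11 in the ileum and 27 in the colon. GF against SPF gave 102 in jejunum 2 and 43 in the ileum, the interaction 332 and the ileal outer-inner difference 11. That last count was 10 without the muscle-rich spots and 0 with 2 bands per roll or the bounding-box centre (edgeR; 886 and 856 genes at an unadjusted p under 0.05, 16 by DESeq2 with the planned bands). The GC offset kept 15 of 16 and gave 27 for FMT against SPF in the duodenum. The slide with both groups gave 987 for GF against SPF in the colon. The interaction gave 974 without GF ileum section 2 and 1092 without that and GF colon section 1.

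In the comparisons with 3 pairs, correlations did not show that the replicate numbers pair the sections. In none of them did every pair of same-numbered sections have deviations from the group mean that correlate above 0.1 (lowest -0.2, highest 0.24). In none of them did all sections correlate best with their own number. With the 2 pairs of the FMT comparisons the deviations of a group mirror each other, so the correlation decides little; same-numbered sections matched best in FMT against SPF in the duodenum (0.04), jejunum 1 (0.12) and colon (0.01). Between other segments of the same status they did both in SPF for duodenum and jejunum 2 (0.16 to 0.29), jejunum 1 and ileum (0.11 to 0.28) and jejunum 2 and ileum (0.14 to 0.24), and in GF for jejunum 1 and jejunum 2 (0.22 to 0.59) and jejunum 1 and colon (0.18 to 0.28), 5 of 20 pairs of segments. SPF sections of the small intestine with the same number also shared a slide, so ileum against duodenum and jejunum 2 against jejunum 1 are paired by slide; with the replicate block they gave 9708 and 2475 genes. Most same-numbered GF sections of the small intestine shared a slide as well. Same-numbered sections of different segments were therefore not shown to be independent in the interaction. With a replicate block, GF against SPF gave 78 in the duodenum, 107 in jejunum 1, 0 in jejunum 2, 4 in the ileum and 259 in the colon. FMT against GF gave 53 in jejunum 1, 0 in jejunum 2 and 17 in the colon, and FMT against SPF 0 in the duodenum, 0 in jejunum 2, 0 in the ileum and 190 in the colon. Behind these zeros of edgeR stood 1354, 522, 939, 704 and 609 genes at an unadjusted p under 0.05; DESeq2 was not run with the block. With the replicate block nested in status the interaction gave 1543, and the other 6 counts were kept. No paired analysis was possible for the DSS sections because each label has 1 section, and none was run for the 2 dark sections.

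Leaving out 1 section at a time gave 8337 to 8875 genes for ileum against duodenum, 1272 to 2405 for jejunum 2 against jejunum 1 and 8508 to 8798 for colon against ileum. GF against SPF ranged over 51 to 251 in the duodenum, 63 to 239 in jejunum 1, 0 to 20 in jejunum 2, 2 to 944 in the ileum and 119 to 656 in the colon. FMT against GF ranged over 0 to 76, 11 to 207, 0 to 24, 0 to 18 and 29 to 2421 in that order, and FMT against SPF over 0 to 90, 0 to 0, 0 to 33, 0 to 1 and 0 to 123. The zeros are edgeR's and had 502 to 2787 genes at an unadjusted p under 0.05. The interaction ranged over 29 to 162 without replicate 1, 2 or 3 of every group. The roll gave 7419 to 8339 in the colon and 2563 to 7141 in the ileum, and its difference between GF and SPF 121 to 209 and 0 to 2190. An arm left with 1 section is assumed to vary like the other groups.

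For the DSS sections, a minimum of 5 CPM gave 260 genes at D12 and 78 at D30, the SPF colon mean as baseline 216 at D12 and 12 at D73, and a pseudocount of 5 CPM 26 at D30 and 44 at D73. TMM factors gave 115, 38 and 64 genes at D12, D30 and D73, within 1.5 times, but moved the split at D30 from 18 higher and 22 lower to 9 and 29. They changed the clock median from 0.294 to 0.159 in the SPF and from 0.182 to 0.244 in the GF dark section, by less than its SD among the other sections (0.532 and 0.79). Against SPF colon section 1, 2 or 3 alone the SPF median was 0.287, 0.742 or 0.123. The median of the clock list in the GF dark section changed sign, to -0.135, when GF colon section 1 alone was the reference; the cause was not tested.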

Other observations

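The test of Hoxb13 against colon RNA, the mean GF effect over segments and the genes named here were chosen after the results were seen.

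Several genes shifted in GF sections along the gut. Averaged over the 5 segments, the GF effect was -2.40 ± 0.10 (log2 ± SE) for Ces2a, -2.63 ± 0.17 for Cyp2c55, -1.68 ± 0.13 for the glutathione transferase Gstm3, -2.35 ± 0.12 for Jchain and -2.09 ± 0.12 for Igha. It was 1.39 ± 0.11 for Il1rl1 and 1.62 ± 0.09 for Lama1, a laminin chain of basement membranes. This fit took the 30 sections as independent, while same-numbered sections correlated between some segments (up to 0.59), so the SEs hold only as far as that is so. Lama1 stood at 2.21 to 4.35 CPM in the 12 GF sections of the small intestine, 0.465 to 1.09 CPM in the SPF and 0.711 to 1.45 CPM in the FMT sections. Il1rl1 stood at 11.3 to 26.4, 2.17 to 7.87 and 1.92 to 5.04 CPM. Both were also higher in the D12 section, with Il1rl1 at 76.1 CPM against 1.17 CPM in sham and Lama1 at 9.79 against 1.25 CPM, without a replicate (all in CPM scaled with TMM factors over all sections).

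Reg3b, an antimicrobial lectin, varied widely among SPF sections, from 78.1 to 2615 CPM in the duodenum and 196 to 2141 CPM in jejunum 2, while GF duodenum sections lay between 235 and 271 CPM. Its GF difference in the duodenum was -1.93 ± 1.13 and did not pass (adjusted p = 0.467, edgeR's quasi-likelihood test). Scand1, a SCAN domain gene, ranged from 4.20 to 333 CPM and the histone H2afj from 25.6 to 636 CPM over the sections, with the high values unevenly spread over compared groups. They partly followed slides. On the slides with GF jejunum 1 sections 1 and 2, every section had Scand1 at 50.4 to 283 CPM and H2afj at 193.5 to 456 CPM. The other GF sections of the small intestine had 7.14 to 26.3 and 25.6 to 76.4 CPM. Slide does not cover all high values: SPF duodenum section 3 had Scand1 at 216 CPM, and the other sections of its slide 8.06 to 10.4 CPM. Scand1 was at 333 CPM in sham, 198 at D12, 70.8 at D30 and 7.69 at D73, and H2afj at 613, 359, 283 and 60.4 CPM. In colon Scand1 was at 8.01, 73.5 and 230 CPM in GF and 4.98 to 7.13 CPM in SPF sections, and H2afj at 69.0, 456 and 636 against 47.5 to 56.4 CPM.

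Hoxb13, which marks the distal hindgut, was counted at 0.281 to 7.06 CPM in the 12 GF sections of the small intestine, against 0 to 0.888 CPM in the SPF and 0 to 0.293 CPM in the FMT sections; in GF colon it was at 268 ± 54.1 CPM. The GF difference passed in the duodenum (2.69 ± 0.48, adjusted p = 0.033, edgeR's quasi-likelihood test) and jejunum 1 (3.62 ± 0.59, adjusted p = 0.025), and not in jejunum 2 (3.21, adjusted p = 0.16) or ileum (2.01, adjusted p = 0.20). If colon RNA or reads were the source, other genes of the colon would come along. The 6 colon genes with at least 100 CPM in GF colon and under 1 CPM in SPF ileum reached a median of 0.0262% of their GF colon level (75th percentile 0.0503%), against 0.658% for Hoxb13, which argues against it, although Aqp8 reached 4.71%. Expression in cells of the GF small intestine may account for the signal and was not tested.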
